A study of Homo sapiens with 22 samples.

How the data were processed

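RNA was measured on 22 arrays of 4 human lung cell lines, 1 array per labelled sample, on the Affymetrix Human Gene 1.0 ST platform. Cells grew on collagen-coated flexible plates and spent 24 h in serum-free medium. They were then left unstretched or stretched by 30% at about 0.5% per second and held there for 4 h or 24 h, per the labels' protocols. The deposited table holds log2 expression values, 1 column per array, and the authors made them with RMA (robust multi-array average, which corrects background, normalizes and summarizes probes), per the submitters' processing notes. The RMA version and any later step are not given in the sources used here. The values were used as deposited. Array medians ran from 4.12 to 4.45 on the 11 arrays of hybridization day 1 and from 5.91 to 6.08 on the 11 arrays of day 2, so levels were not set against each other across days. CCL-151 was hybridized on day 1 and the other 3 lines on day 2, so each stretch effect was computed within a day.

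Of 33297 probe sets, 19460 had 1 gene symbol in the platform annotation, 1754 had several and 12083 were not listed there. Of the probe sets with 1 symbol, 19429 were matched by gene identifier to a current gene table and 31 were not; no symbol changed by that match. A gene was represented by its probe set with the highest mean over the 22 arrays, which gave 18417 genes. A gene was tested if at least 2 arrays held it above the 50th percentile of all probe sets on that array, which left 13775 genes. Probe sets with several symbols or none listed were tested apart and are named for no gene. For arrays, the number of arrays limits the precision.

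Groups came from the labels: A549 at 4 h (2 control, 2 stretch), 16HBE14o- at 4 h (2 control, 1 stretch), CCL-153 at 4 h (2 control, 2 stretch), and CCL-151 at 4 h (3 control, 2 stretch) and at 24 h (3 control, 3 stretch). Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) in 1 fit of all 22 arrays with 10 group means and 12 residual degrees of freedom, two-sided. P-values were adjusted by Benjamini-Hochberg over the 13775 genes and called at 0.05. The lone stretched 16HBE14o- array was assumed to vary like the arrays of the other groups. Contrasts were the 5 stretch effects, 24 h against 4 h controls of CCL-151, 24 h against 4 h stretch effects of CCL-151, epithelial against fibroblast lines, the mean of 4 lines at 4 h, an F-test over the 4 lines and 6 pairs of lines.

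A fixed collection of 28 gene lists (21 of responses, 7 of cell type markers) was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists within a contrast; camera with an estimated correlation and the fry test were alternatives. The fry test asks whether a list's genes move, on balance, one way and compares the list with no other genes. Adjusted p-values of genes and lists below are from limma unless stated.

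The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Under that rule, each stretch comparison named up to 12 of the highest rises and 12 of the largest falls among called genes whose stretched arrays all lay beyond all control arrays. With fewer than 5 such genes it named the 5 smallest p-values instead. The other comparisons named 6 genes each, lists named up to 4 members of smallest p, and a fixed set of genes known from stretch studies could be named throughout (CCN1, CCN2, EGR1, FOS, ATF3, IL6, CXCL8, PTGS2, HMOX1, THBS1, HBEGF, MYC and DUSP1 where tested); 1 further result of that set is not reported here. Unnamed open reading frames and sex-linked marker genes were not named. Genes outside this rule are said to be chosen after their values were seen.

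Levels of genes of other lines on day 2 were measured after the data had been seen. For each of A549, 16HBE14o- and CCL-153, the 50 genes most above the other 2 lines were taken, with every own array at least 0.5 log2 above every other array. An array's level of those genes was the median of its linear signal, less the lowest array's, as a percentage of the mean over the line's own arrays. As an added alternative, the contribution of other lines predicted from these percentages was subtracted before the fit.

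The alternatives tried were median centring, quantile normalization over all arrays or within a day, no filter or a 75th percentile filter, the mean of a gene's probe sets or each probe set alone, fits of 1 day or 1 line, other variance settings, array weights, a replicate block and leaving out each array. Steps were tested on simulated values with 200 of 13775 genes changed. Changes of 1 log2 were recovered for 46.3% of changed genes in A549, 34.3% in 16HBE14o-, 52.2% in CCL-153, 65.7% in CCL-151 at 4 h and 76.1% at 24 h. Changes of 2 log2 were recovered for 95.5%, 80.3%, 93.9%, 93.9% and 98.5%, and changes of 0.5 log2 for 10.4%, 1.49%, 4.48%, 13.4% and 17.9%. False calls made up 4.72%, 9.41%, 4.76%, 3.36% and 3.76% of all calls in the same order. In the CCL-153 simulation, the 1 list shifted by 0.5 log2 had an adjusted p of 2.74e-07 by camera and 0 of 27 other lists were called. Noise was drawn independently for each gene, with the same spread on all arrays. These simulations therefore cannot tell how the list test treats genes that vary together. Nor do they cover arrays that stand apart from their group. Simulated mixtures of lines on 11 arrays were estimated within 3.18 percentage points. These mixtures followed the estimate's own assumptions, with a line's genes set to the lowest day 2 value in the other lines. The error on real arrays can therefore be larger.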

Results

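The study measured what a sustained 30% stretch did to gene expression in human lung epithelial and fibroblast lines. A549 is an alveolar-type lung carcinoma line and 16HBE14o- an immortalized bronchial epithelial line. CCL-153 and CCL-151 are lung fibroblast lines, and the labels disagree on whether CCL-151 is fetal or juvenile. All 4 lines were sampled after 4 h and CCL-151 also after 24 h, each beside unstretched controls of the same time. The groups held 1 to 3 arrays, 22 in all, and values are log2 signals. In A549 both stretched arrays carry the replicate letter B and both controls C. The design text calls the replicates technical, so p-values measure only the spread between these arrays.

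Within groups, arrays correlated at 0.980 to 0.996 over all probe sets, which are not independent replicates, except in the 4 h controls of CCL-151. There, arrays a and c correlated with array b at 0.915 and 0.881 and with each other at 0.982. Arrays a and c also had narrower value distributions (interquartile ranges 2.58 and 2.49) than array b (3.09).

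Genes typical of one line were measurable on arrays of other lines hybridized on the same day. The 50 genes most specific to A549 stood at 37.2% of their A549 level on the stretched 16HBE14o- array, against 0.701% ± 0.992 (SD, n = 2) in its controls. In CCL-153 they stood at 19.7% ± 0.601 in controls and 2.62% ± 0.234 in stretched cells (SD, n = 2 each). The 50 genes specific to 16HBE14o- stood at 7.46% ± 0.199 in stretched CCL-153 cells and 0.989% ± 0.401 in controls. In A549 they stood at 3.23% ± 0.478 in controls and 0.410% ± 0.215 in stretched cells. The 50 genes specific to CCL-153 stood at 12.3% ± 8.26 in 16HBE14o- controls and 0.770% on the stretched array.

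**Figure D1:**
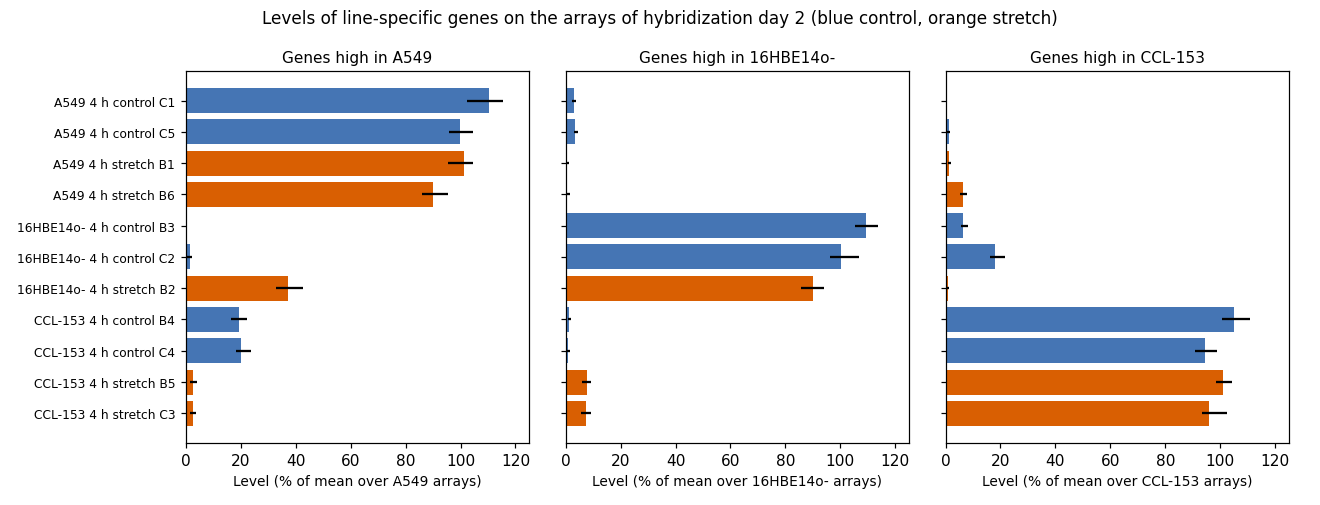
Median level of 50 line-specific genes on each of the 11 arrays of hybridization day 2, as a percentage of the mean over the line's own arrays (bars; black lines, middle 50% of the genes; blue, control; orange, stretch). The A549 genes reach 37.2% on the stretched 16HBE14o- array.

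In A549 cells, 4 h of stretch raised metallothionein genes, which encode small cysteine-rich proteins that bind zinc and copper. MT1X rose by 3.15 log2 (SE 0.22, adjusted p = 8.98e-07, limma), from 8.66 ± 0.11 to 11.81 ± 0.05 (SD, n = 2 each). MT1F rose by 3.10, MT1G by 1.95, MT1E by 1.83, MT2A by 1.82 and MT1H by 1.67. INSIG1, a sterol-regulated brake on cholesterol synthesis, rose by 1.53 (SE 0.18, adjusted p = 0.000449), and MVD, an enzyme of the mevalonate pathway, by 1.04 (SE 0.17). Further rises were the chemokine CCL20 (1.45, SE 0.27), the small heat shock protein HSPB8 (1.36, SE 0.24), the stress-induced pseudokinase TRIB3 (1.28, SE 0.20) and the matricellular protein CCN2 (0.96, SE 0.16).

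Genes that fell in stretched A549 cells included several epithelial and interferon-induced genes. The list of 16 epithelial markers did not pass with an estimated correlation, and its median was 0.087 after subtraction of other lines. MAL2, a protein of apical transport, fell by 2.99 (SE 0.27), MACC1 fell by 1.99 (SE 0.31), the epithelial integrin subunit ITGB6 fell by 1.53 (SE 0.24) and the cytokine IL1A fell by 1.38 (SE 0.19). The chloride channel CFTR fell by 1.25 and the adhesion protein EPCAM fell by 0.86. The interferon-induced genes MX1, IFIT1 and IFIH1 fell by 1.34, 1.32 and 1.03. Beside these falls, the 50 genes specific to 16HBE14o- had a median log2 change of -0.79, with 8 called lower; these 8 were MAL2, MACC1, ITGB6, IL1A, CFTR, EPCAM, MX1 and IFIT1. After subtraction of the estimated signal of other lines, an alternative chosen after seeing the data, MAL2 still passed at -2.10. The subtraction was set by the median of the 50 genes, so it can leave part of that signal in MAL2. ST8SIA4 and PER2, outside those 50 genes, fell by 1.12 and 0.67 and still passed, at -1.12 and -0.65. ITGB6 (-0.12), EPCAM (-0.25), MX1 (-0.26), IFIT1 (-0.18) and IFIH1 (-0.54) no longer passed, and CFTR, IL1A and MACC1 turned to 0.52, 0.52 and 0.24.

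Of 11 metallothionein and zinc genes measured in A549, 6 rose (8 adjusted over the list alone; median 1.67; camera adjusted p = 1.32e-41, and adjusted p = 0.000188 with an estimated correlation). Of 19 cholesterol synthesis genes, 2 rose (7 adjusted over the list alone; median 0.52; adjusted p = 5.80e-21, and adjusted p = 0.0283 with an estimated correlation). Of 23 inflammatory genes, CCL20 and NFKB2 rose and IL1A fell (5 and 1 adjusted over the list alone; adjusted p = 0.00322 with an estimated correlation). Of 23 interferon-stimulated genes, 3 fell (8 adjusted over the list alone; median -0.28; adjusted p = 0.000417 with an estimated correlation), but after that subtraction the median was 0.0036 and the list did not pass. Of 29 immediate early genes, SRF rose by 0.75 (4 adjusted over the list alone; median 0.35; adjusted p = 0.00431 with an estimated correlation). The 30 matrix genes had a median of 0.39, with adjusted p = 0.13 with an estimated correlation, beside a median of 0.92 for the 50 genes specific to CCL-153. CXCL8 (1.23, adjusted p = 0.111), HBEGF (1.15, adjusted p = 0.0772) and HMOX1 (0.91, adjusted p = 0.907) did not pass; after the subtraction CXCL8 (1.59) and HBEGF (1.39) passed and HMOX1 (0.91) did not.

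In all, 34 of 13775 genes were called in A549, 23 higher and 11 lower, and 457 had an unadjusted p under 0.05 against 689 expected by chance. The count was 11 without control C1, 13 without control C5, 16 without stretched array B1 and 15 without B6, and it was 200 without the CCL-151 4 h controls a and c and 213 in a fit of A549 arrays alone. CCL-151 controls a and c enter the A549 comparison only through the shared estimate of spread, so the higher count without them came from that estimate. The 457, fewer than expected by chance, can reflect it too and does not measure how little changed. The split of calls was 40 higher and 10 lower after quantile normalization over all 22 arrays. Subtraction of other lines left 28 calls, 24 of them among the 34, and CCN2 (0.68) no longer passed.

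In 16HBE14o- cells, metallothionein genes were again among the highest rises on the lone stretched array. MT1M rose by 4.70 (SE 0.43, adjusted p = 9.71e-06) from 5.39 ± 0.05 (SD, n = 2) to 10.10, and MT1X by 2.90 (SE 0.27). HMOX1, the heme-degrading enzyme heme oxygenase, rose by 2.82 (SE 0.40, adjusted p = 0.000669), but by 1.70 after subtraction of the estimated signal of other lines, which did not pass; its control level was 9.70 in A549 and 7.68 in 16HBE14o-. The bile acid transporter SLCO1B3 rose by 3.09, the kidney injury molecule HAVCR1 by 2.92, HGD, an enzyme of tyrosine breakdown, by 2.88 and AGR2 by 2.87. TMEM156 rose by 2.83, the growth factor NRG1 by 2.77, KYNU and NTS by 2.75 each, and the phospholipase PLA2G4A from 5.69 ± 0.23 (SD, n = 2) to 8.69. PTGS2, the inducible prostaglandin synthase, rose from 5.96 ± 0.11 to 7.96 (SE of the difference 0.21). Beside these rises, 49 of the 50 genes specific to A549 were called higher, with a median of 2.35.

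The falls in 16HBE14o- were led by genes of mesenchymal cells and extracellular matrix. The phosphodiesterase PDE5A fell by 3.35 (SE 0.70), IGFBP5 fell by 3.09, the proteoglycan DCN fell by 3.04, the urea transporter SLC14A1 fell from 8.07 to 5.07 and the collagens COL6A3, COL1A2 and COL12A1 fell by 2.93, 2.83 and 2.61. PCDH18, LRRC17 and the receptor PDGFRA fell by 2.94, 2.90 and 2.81, the collagen cross-linking enzyme LOX fell by 2.63 and EDIL3 fell by 2.53. Of 30 matrix genes, 10 fell (17 fell and 1 rose adjusted over the list alone; median -0.90; adjusted p = 5.62e-24, and adjusted p = 0.0656 with an estimated correlation). Of 20 fibroblast markers, 7 fell and S100A4, which belongs to the 50 genes specific to A549, rose (12 and 1 adjusted over the list alone; adjusted p = 0.0656 with an estimated correlation). Beside these falls, the 50 genes specific to CCL-153 had a median of -1.95, with 23 called lower.

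Of 11 metallothionein and zinc genes in 16HBE14o-, 8 rose (8 adjusted over the list alone; median 1.43; adjusted p = 0.00209 with an estimated correlation). Of 20 genes of the oxidative stress list, 9 rose (13 adjusted over the list alone; median 0.92; adjusted p = 0.0142 with an estimated correlation), including the transporter ABCC2 (2.51, SE 0.22) and the aldo-keto reductases AKR1C1 (1.59) and AKR1C3 (1.78), beside the A549-specific genes above; after subtraction the median was 0.22 and the list no longer passed with an estimated correlation. Of 24 TGF-beta and BMP response genes, ID1 (1.38), SMAD6 (0.96) and PMEPA1 (8.88 to 9.88) rose (6 rose and 1 fell adjusted over the list alone; adjusted p = 0.0349 with an estimated correlation). Of 23 interferon-stimulated genes, IFI44L fell by 1.15 (3 adjusted over the list alone; median -0.50; adjusted p = 0.00209 with an estimated correlation); after subtraction the median was -0.10 and the list no longer passed with an estimated correlation. HBEGF (0.29), CXCL8 (0.35) and EGR1 (-0.38) did not pass. After subtraction they were at 0.78, 0.78 and 0.28 and did not pass either. Genes specific to 16HBE14o- shifted upward as well, MACC1 from -0.33 to 0.16. The list of 23 inflammatory genes passed as higher with an estimated correlation, before subtraction and after it (median 0.42 after).

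In all, 227 genes were called in 16HBE14o-, 186 higher and 41 lower, with 819 under an unadjusted p of 0.05; the single stretched array gives no replicate check within its group. Leaving out control C2 left 137 calls, leaving out the CCL-151 4 h controls a and c gave 671, a fit of the line's own arrays 770, and subtracting the estimated signal of other lines left 11, all higher, with HGD, PLA2G4A and PTGS2 at -0.13, -0.19 and -0.086, COL12A1, EDIL3, LOX, LRRC17 and PCDH18 at 0.27 to 0.69 and the matrix list at a median of 0.20.

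In CCL-153 fibroblasts, metallothionein genes, HMOX1 and a few chaperone genes rose. MT1M rose by 4.49 (SE 0.35, adjusted p = 6.18e-06), from 5.17 ± 0.19 to 9.65 ± 1.03 (SD, n = 2 each). MT1X rose by 2.82, MT1G by 2.53, MT1F by 2.48 and MT1E by 2.02. HMOX1 rose by 2.58 (SE 0.33, adjusted p = 0.000325). The stress-inducible chaperone HSPA6 rose by 3.83 (SE 0.86, adjusted p = 0.041), with stretched arrays far apart (9.53 ± 2.89, SD, n = 2), and the co-chaperone DNAJA4 by 2.74 (SE 0.41).

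Further rises in CCL-153 were ANKRD1, a stretch-responsive nuclear cofactor (2.24, SE 0.31), the EGFR ligand HBEGF (1.79, SE 0.24), the chemokine CXCL8 (1.70, SE 0.28) and the microRNA gene MIR221 (2.24, SE 0.41). IL1A (2.19, SE 0.19) and ITGB6 (2.09, SE 0.24) also rose, beside the 50 genes specific to 16HBE14o-, whose median was 1.09 with 26 called higher. The falls were ceruloplasmin, CP, which fell by 2.16 (SE 0.24), the prostaglandin-degrading enzyme HPGD, which fell by 1.97, CNTN1, which fell by 1.87, and HGD and AGR2, which fell by 1.83 each. TM4SF18 fell by 1.81, the liver-type secreted protein FGL1 fell from 6.38 to 4.57, the vitamin D hydroxylase CYP24A1 and TM4SF20 fell by 1.76 each, the fibrinogen chains FGB and FGG fell by 1.72 and 1.65, and ANXA13 fell by 1.65. Beside these falls, the 50 genes specific to A549 had a median of -1.47, with 40 called lower.

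Of 11 metallothionein and zinc genes in CCL-153, 7 rose (8 adjusted over the list alone; median 1.69; adjusted p = 0.000466 with an estimated correlation). Of 23 inflammatory genes, IL1A, TNFAIP3 (1.79) and CXCL8 rose (6 rose and 1 fell adjusted over the list alone; adjusted p = 0.00142 with an estimated correlation). Of 17 growth factor genes, HBEGF, EPGN (1.21) and TGFA (1.27) rose (6 adjusted over the list alone; adjusted p = 0.00145 with an estimated correlation). IL1A and EPGN belong to the 50 genes specific to 16HBE14o-. Of 15 heat shock genes, HSPB8 rose by 1.18 (4 adjusted over the list alone; median 0.53; adjusted p = 1.45e-10, but adjusted p = 0.25 with an estimated correlation). Of 23 interferon-stimulated genes, BST2 (1.45), IFI27 (1.12) and MX1 (1.07) rose (4 adjusted over the list alone; adjusted p = 0.0344 with an estimated correlation), beside the 16HBE14o- genes above, which include BST2 and MX1. After subtraction of other lines the list passed in the opposite direction, with a median of -0.23, also with an estimated correlation, and MX1 was at -0.23. Genes specific to CCL-153 were lowered by the subtraction too, DCN from -0.031 to -0.22, so part of this reversal can come from removing too much. Of 16 epithelial markers, EPCAM (1.72), CDH3 (1.42) and CDH1 (1.16) rose and KRT7 fell by 0.86 (6 and 2 adjusted over the list alone; adjusted p = 0.419 with an estimated correlation). EPCAM and CDH3 belong to the 16HBE14o- genes above, and EPCAM was at 0.34 after subtraction, which did not pass.

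In all, 151 genes were called in CCL-153, 63 higher and 88 lower, with 702 under an unadjusted p of 0.05. The count was 84 without control B4, 59 without control C4, 72 without stretched array C3, 519 without the CCL-151 4 h controls a and c and 848 in a fit of the line's own arrays. Subtracting the estimated signal of other lines left 15, all higher, of which 14 were among the 151, with ANXA13, FGB, FGL1 and HGD turned to 0.36 to 0.65. CXCL8 (0.98), HSPA6 (3.78), DNAJA4 (2.23), MIR221 (2.05), IL1A (0.57) and ITGB6 (0.30) no longer passed after it, while HMOX1 (3.24), ANKRD1 (2.43) and HBEGF (1.43) did. HSPB8 (1.07), TNFAIP3, EPGN, TGFA, BST2, IFI27, CDH3, CDH1 and KRT7 no longer passed either.

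In CCL-151 fibroblasts at 4 h, 10 genes rose and led with the same kinds of genes. MT1M rose by 3.46 (SE 0.32, adjusted p = 0.000138), from 4.87 ± 0.49 (n = 3) to 8.33 ± 0.12 (SD, n = 2), and HMOX1 from 6.07 ± 0.33 to 9.07 ± 0.27 (SE of the difference 0.30, adjusted p = 0.000196). The metallothioneins MT1X, MT1G and MT1E rose by 1.81, 1.73 and 1.19, and the zinc exporter SLC30A1 by 1.69 (SE 0.24). The co-chaperone DNAJB1 rose by 1.85 (SE 0.29), HBEGF by 1.62 (SE 0.22), the EGFR feedback inhibitor ERRFI1 by 1.30 (SE 0.21) and the apoptosis effector BAK1 by 0.84 (SE 0.14). MYC (0.81, adjusted p = 0.0961) and IL6 (0.86, adjusted p = 0.227) did not pass.

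Of 11 metallothionein and zinc genes in CCL-151, 5 rose (7 adjusted over the list alone; adjusted p = 1.69e-09, but adjusted p = 0.105 with an estimated correlation), with a median of 0.75 against 0.11 for all tested genes. Of 15 heat shock genes, DNAJB1 rose (14 adjusted over the list alone; median 0.96; adjusted p = 1.05e-08, but adjusted p = 0.462 with an estimated correlation). Of 20 oxidative stress genes, HMOX1 rose (13 adjusted over the list alone; median 0.54; adjusted p = 7.79e-06, but adjusted p = 0.475 with an estimated correlation). Median centring moved the median change of all genes from 0.11 to 0.22, and that of the metallothionein and zinc list to 0.86.

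In CCL-151 at 4 h, 2955 genes had an unadjusted p under 0.05. The 10 calls became 5 without stretched array a, 4 without stretched array c and 10370 without control b; leaving out controls a and c instead gave 22 calls, 11 higher and 11 lower, with 7 of the 10 among them.

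After 24 h of stretch in CCL-151, limma called 0 genes (91 under an unadjusted p of 0.05). The 5 genes of smallest p, none of which passed, were MT1G (0.78, SE 0.17), CEMIP (-0.76, SE 0.22), TMEM154 (0.63, SE 0.19), NEFM (0.51, SE 0.14) and ZNF385D (0.43, SE 0.13), all at an adjusted p of 0.999. HMOX1 stood at 6.40 ± 0.05 in stretched cells and 5.94 ± 0.18 in controls (SD, n = 3 each). The 11 metallothionein and zinc genes all had values above 0, with a median of 0.29 (3 rose adjusted over the list alone; adjusted p = 3.85e-13, and adjusted p = 0.0333 with an estimated correlation). The 20 oxidative stress genes had a median of 0.26 (adjusted p = 6.54e-12, but adjusted p = 0.435 with an estimated correlation). A fit of the 24 h arrays alone, chosen after seeing the data, called CEMIP, with 1061 genes under an unadjusted p of 0.05; a fit with array weights called 7057, with weights that did not settle.

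The stretch effect in CCL-151 was compared between times. HMOX1 had an effect lower by 2.54 at 24 h than at 4 h (-2.54, SE 0.40, adjusted p = 0.0976), and MT1M differed by -2.65 (SE 0.43, adjusted p = 0.0976); neither passed. Over all genes limma called 0, with 346 under an unadjusted p of 0.05. HMOX1 was the 1 gene called in a fit of CCL-151 arrays alone, and 7046 genes were called without 4 h control b. The metallothionein and zinc list had a median difference of -0.33 (5 lower adjusted over the list alone; adjusted p = 2.16e-07, but adjusted p = 0.258 with an estimated correlation), and the heat shock list -0.62 (2 lower adjusted over the list alone; adjusted p = 0.488 with an estimated correlation).

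Between 24 h and 4 h controls of CCL-151, limma called 0 genes, although 6584 had an unadjusted p under 0.05; the smallest adjusted p was 0.0545. The 34 cell cycle genes had a median of 0.65 (23 higher adjusted over the list alone; adjusted p = 6.97e-05, but adjusted p = 0.57 with an estimated correlation), including the cyclin CCNB2 (4.62 to 5.61, SE of the difference 0.19) and the mitotic kinesin KIF20A (1.32, SE 0.26). The 19 cholesterol synthesis genes had a median of 0.69 (15 higher and 1 lower adjusted over the list alone; adjusted p = 0.57 with an estimated correlation). Beside these medians, all genes had a median of 0.13, and the 4 h controls a and c stood apart from control b. The count was 11121 without control b, 2098 after quantile normalization over all arrays and 2764 under the stricter filter.

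Averaged over the 4 lines at 4 h, 77 genes were called, all higher, with 898 under an unadjusted p of 0.05. MT1M rose by 3.53 (SE 0.18, adjusted p = 1.25e-08), HSPA6 by 2.75 (SE 0.45), MT1X by 2.67 (SE 0.11), HMOX1 by 2.33 (SE 0.17), MT1F by 2.16 (SE 0.12) and MT1G by 1.97 (SE 0.11). HBEGF rose by 1.21 (SE 0.13), ANKRD1 by 1.55 (SE 0.16), HSPB8 by 1.15 (SE 0.12) and INSIG1 by 0.79 (SE 0.09).

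In the 4-line mean, 8 of 11 metallothionein and zinc genes rose (8 adjusted over the list alone; adjusted p = 0.000163 with an estimated correlation). Of 15 heat shock genes 4 rose (12 adjusted over the list alone; adjusted p = 0.0412 with an estimated correlation), of 29 immediate early genes 5 rose (17 adjusted over the list alone; adjusted p = 0.00193 with an estimated correlation), and of 23 inflammatory genes 7 rose (11 adjusted over the list alone; adjusted p = 0.00044 with an estimated correlation), among them TNFAIP3 (0.76) and CXCL8 (0.96). Of 17 growth factor genes 2 rose (6 adjusted over the list alone; adjusted p = 0.000815 with an estimated correlation). The 23 interferon-stimulated genes all had values below 0, with a median of -0.17 (4 lower adjusted over the list alone; adjusted p = 0.000815 with an estimated correlation). The count of 77 was 49 without A549 stretched array B1, 45 without CCL-153 control C4 or stretched array C3, 49 and 47 without CCL-151 stretched arrays a and c, and 3334 without CCL-151 control b. It was 127 (126 higher) after quantile normalization within days and 732 (359 higher) without CCL-151 controls a and c, and subtraction of other lines gave 87 (84 higher and 3 lower, 61 among the 77).

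**Figure D2:**
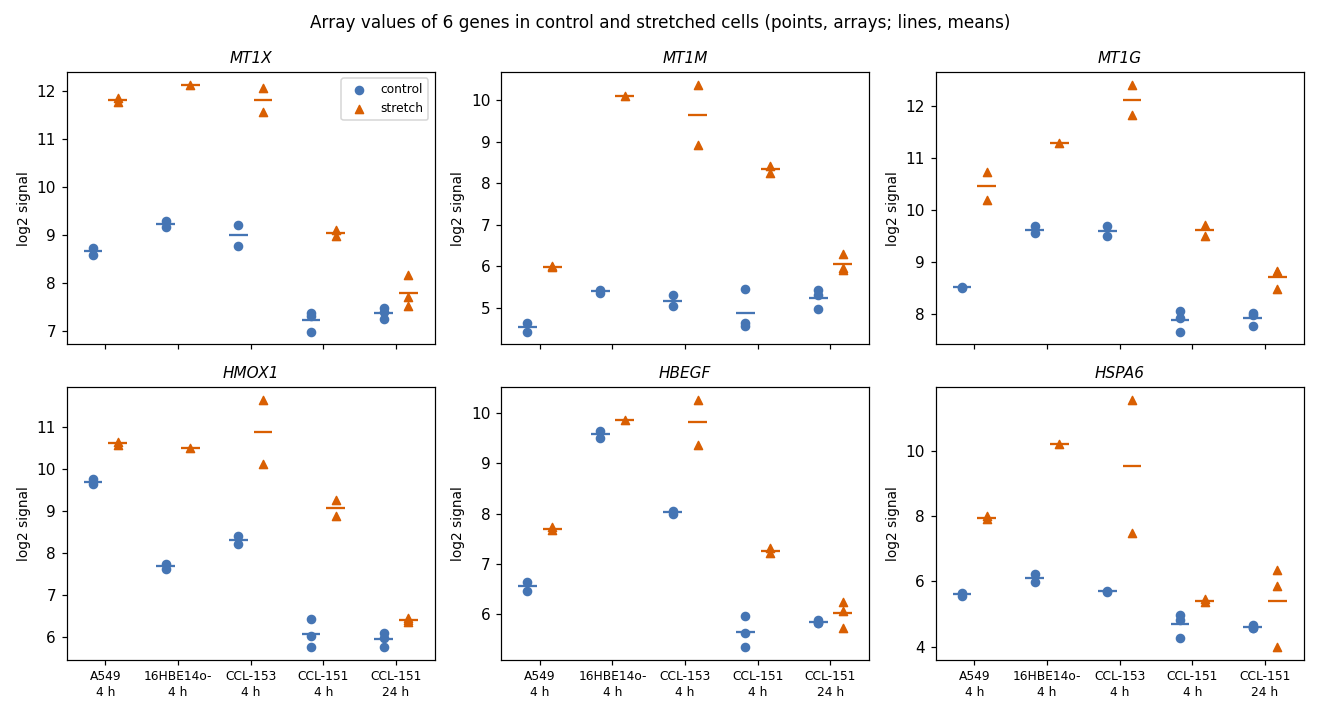
Log2 signal of 6 genes on each array by cell line and time (circles, control; triangles, stretch; lines, group means). At 4 h the stretched arrays of every line lie above its controls for all 6 genes; levels of CCL-151 and the other lines come from different hybridization days.

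The stretch effect differed between epithelial and fibroblast lines for 130 genes (110 higher in epithelial lines, 20 lower; 738 under an unadjusted p of 0.05). The largest differences were HGD (2.48, SE 0.20), CP (2.40, SE 0.25), SLCO1B3 (2.37, SE 0.26), FGB (2.35, SE 0.29), AGR2 (2.34, SE 0.16) and MAL2 (-2.54, SE 0.29). Beside these, 48 of the 50 genes specific to A549 were called higher, with a median of 1.96. Of 23 interferon-stimulated genes, 5 were lower in epithelial lines (10 adjusted over the list alone; median -0.57; adjusted p = 0.00798 with an estimated correlation), led by MX1 (-1.43), beside a median of -0.98 for the genes specific to 16HBE14o-. The metallothionein and zinc list was not called (adjusted p = 0.12), with a median of -0.28 and a mean of 0.09 in opposite directions, although MT1F differed by 1.08 (SE 0.24, adjusted p = 0.0465). After subtraction of other lines the list was called as higher in epithelial lines at the preset correlation, with a median of -0.083 of the opposite sign, but was not called with an estimated correlation (adjusted p = 0.193 with an estimated correlation). The count was 5019 without CCL-151 control b, 425 without controls a and c, and 0 (348 under an unadjusted p of 0.05) after subtracting the estimated signal of other lines, with FGB and HGD at -0.24 and -0.12 and the interferon list at a median of 0.11.

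Across the 4 lines, an F-test called 216 genes (864 under an unadjusted p of 0.05), led by AGR2, NRCAM, HGD, CNTN1, SPP1 and C5. AGR2, for example, had effects of -0.14 in A549, 2.87 in 16HBE14o-, -1.83 in CCL-153 and -0.14 in CCL-151. Between pairs of lines, 239 genes differed between 16HBE14o- and CCL-153, 174 between A549 and 16HBE14o-, 107 between 16HBE14o- and CCL-151, 48 between A549 and CCL-153, 42 between CCL-153 and CCL-151, and 4 between A549 and CCL-151. These 4, named after their values were seen except where a rule above names them, were MAL2 (-2.87), MT1F (2.36), RAB33A (1.53) and MT2A (1.37). The F-test count was 143 without 16HBE14o- control C2, 140, 131, 141 and 139 without CCL-153 arrays B4, C4, B5 and C3, 8806 without CCL-151 control b and 769 without controls a and c. After subtraction of other lines it was 3 (MAL2, MT1F and MT2A), with 327 under an unadjusted p of 0.05. MAL2 belongs to the genes specific to 16HBE14o-, and the subtraction can leave part of that line's signal in it. Its call after subtraction therefore does not decide whether its stretch effect differed between lines.

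The rises shared between lines were mostly metallothionein genes. A549 and 16HBE14o- shared 9 rises (0.311 expected of independent lists), all of them metallothionein genes or pseudogenes. The stretched 16HBE14o- array held A549 genes at 37.2%, and the subtraction of other lines does not cover RNA of stretched A549 cells. A549 and CCL-153 also shared 9 (0.105 expected), 16HBE14o- and CCL-153 shared 13 (0.851 expected), including HMOX1, SLC30A1 and ANKRD1 (in 16HBE14o- none passed after subtraction of other lines, where HMOX1 fell from 2.82 to 1.70 while SLC30A1 went from 1.43 to 1.45 and ANKRD1 from 1.66 to 1.77), and CCL-153 and CCL-151 shared 7 (0.0457 expected), including HBEGF and HMOX1. CCL-151 shared 3 with A549 and 6 with 16HBE14o- (0.0167 and 0.135 expected). Of 77 genes called in both 16HBE14o- and CCL-153, 64 moved in opposite directions, and 40 of these belong to the 50 genes specific to A549. After subtraction of other lines, the 11 and 15 genes called in these lines were all higher. Of 17 called in both A549 and CCL-153, 7 moved in opposite directions, all of them among the 50 genes specific to 16HBE14o-. Across genes, which are not independent replicates, effects correlated at 0.248 between A549 and CCL-153, -0.197 between 16HBE14o- and CCL-153 and 0.682 between 4 h and 24 h in CCL-151. The last was 0.382 without CCL-151 24 h control b, and that of 16HBE14o- and CCL-153 was -0.131 without CCL-153 stretched array B5. In CCL-151, 24 h control b deviated from its group like the 4 h controls a and c (r = 0.739 and 0.765 across genes). The 0.682 can therefore hold a pattern of the control arrays. The other pairs of 4 h effects correlated at -0.0413 (A549 and 16HBE14o-), -0.0456 (A549 and CCL-151), -0.0364 (16HBE14o- and CCL-151) and 0.0243 (CCL-153 and CCL-151), each of which changed sign with some array left out.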

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

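The tests of swapped arrays, of a response of each line, of subtraction on the metallothioneins, of SLC30A1, of hours in culture and of other splits of the arrays were chosen after the results they bear on were seen; those of genes held out, of scaling and of compressed values were written before.

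Stretch effects at 4 h differed between the 4 lines by a test of the difference itself. The F-test called 216 genes, and the epithelial lines differed from the fibroblast lines in 130. By pairs, 174 genes differed between A549 and 16HBE14o-, 48 between A549 and CCL-153, 4 between A549 and CCL-151, 239 between 16HBE14o- and CCL-153, 107 between 16HBE14o- and CCL-151, and 42 between CCL-153 and CCL-151. The largest epithelial minus fibroblast differences were HGD 2.48, CP 2.40, SLCO1B3 2.37, FGB 2.35, AGR2 2.34 and MAL2 -2.54. Lists that differed had medians of 0.24 (oxidative stress), -0.28 (endoplasmic reticulum chaperones), -0.32 (heat shock), -0.44 (matrix), 0.11 (cholesterol synthesis), -0.57 (interferon) and 0.053 (TGF-beta and BMP); of these only the interferon list passed with an estimated correlation. After subtraction of the estimated signal of other lines the calls were 0 by limma for epithelial against fibroblast lines (348 under an unadjusted p of 0.05) and 3 in the F-test, and the oxidative stress, matrix and interferon medians turned to -0.15, 0.0028 and 0.11.

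One pattern is that genes of other day 2 lines moved between stretched and control arrays of A549, 16HBE14o- and CCL-153. Among 74 A549 genes held out of the 50-gene set, the median level on the stretched 16HBE14o- array was 33.8% of that in A549 (middle 50% of genes 30.1% to 38.5%), as RNA of another line in some samples would need. The same array held the 50 genes specific to 16HBE14o- at 90.1%, with a median change of -0.21. A mixture with so much A549 RNA would leave these own genes lower, so the percentages are not exact shares of RNA. Arrays swapped whole between lines are argued against, since over all tested genes, which are not independent replicates, each of the 11 arrays had a higher mean correlation with the other arrays of its own line than with those of any other day 2 line, by at least 0.0643 (the stretched 16HBE14o- array). A response of each line to stretch stays open for the changes: the middle 50% of the A549 genes' levels spanned 0.260 of their median, a bound set after the quartiles were seen that a coordinated response could also meet. A response to stretch would not itself give the levels on unstretched arrays. There the A549 genes stood at 19.3% and 20.2% in CCL-153, and the CCL-153 genes at 6.49% and 18.2% in 16HBE14o-. A line's own unstretched expression, lowered by stretch, could give these levels and was not tested apart. RNA of other lines may account for many of the calls in 16HBE14o- and CCL-153, and the values do not tell at which step it could have entered. The predicted signal of other lines reached at least 50% of the change, in the same direction, for 203 of 227 calls in 16HBE14o-. It did so for 113 of 151 in CCL-153 and for 7 of 34 in A549. The levels behind that prediction were estimated on these same arrays.

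Another pattern is the rise of the metallothionein and zinc list at 4 h in all 4 lines at the preset correlation; in CCL-151 it did not pass with an estimated correlation (adjusted p = 0.105). RNA of another unstretched day 2 line is argued against as its whole cause, since after subtraction the list's median was at least 0.982 of its size before in each of the 3 day 2 lines. The subtraction used levels of unstretched arrays alone, so it cannot decide on RNA of another stretched line. Such RNA stays open as part of the rise, above all on the stretched 16HBE14o- array, where A549 genes stood at 37.2%. Scaling between arrays is argued against too, since the lowest median over 4 lines and 3 scalings was 0.617. Probe sets shared between metallothionein paralogs leave open how many family members rose, although SLC30A1, a zinc exporter outside the family, was called in 3 lines. A response of lung cells to sustained stretch, or to the handling that goes with it, may raise these genes; the design has no handling control among the labelled groups to tell the 2 apart.

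Within CCL-151, the stretch effect at 24 h differed from that at 4 h for 17 of 28 lists at the preset correlation and for 0 with an estimated correlation. Medians of the difference were -0.39 (YAP and TAZ targets), -0.33 (actin and contractile), -0.29 (oxidative stress), -0.32 (endoplasmic reticulum chaperones), -0.30 (ATF4 stress), -0.62 (heat shock), -0.34 (matrix), -0.37 (proteolysis), -0.29 (cell cycle), -0.29 (hypoxia and glycolysis), 0.14 (interferon), -0.22 (TGF-beta and BMP), -0.33 (metallothionein and zinc), -0.36 (adhesion), -0.26 (growth factors), -0.28 (ribosome) and 0.20 (epithelial markers). Without the 4 h controls a and c, 4 lists were called at the preset correlation, and medians turned to 0.067 (actin and contractile), 0.22 (oxidative stress), 0.073 (endoplasmic reticulum chaperones), 0.16 (cell cycle), -0.12 (interferon), 0.044 (adhesion), 0.028 (ribosome) and -0.42 (epithelial markers).

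A further pattern is that the CCL-151 4 h controls a and c stand apart from control b. Compressed values on these arrays were not decided on. After quantile normalization within days 6735 genes still had an unadjusted p under 0.05 between 24 h and 4 h controls by limma (6584 before, 689 by chance). A change with time could also keep that number high, and a and c were not set against b. Control b and both 4 h stretched arrays correlated more with the 24 h controls than with a and c, by at least 0.0993. This does not decide on hours in culture, since a and c were picked because they stood apart, which favoured that outcome. Arrays a and c and control b carry the same 4 h label. The labels name no biological difference between these arrays, so none was tested. A difference in handling or in RNA quality of arrays a and c stays open as a candidate cause and was not tested.

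The 6 arrays of each CCL-151 comparison with 3 arrays per group can be split in 10 ways, too few for a share under 0.05. Between 24 h stretch and control the real split called 0 genes and the highest other 0, so 10 of 10 splits gave as many. Any split gives at least 0, so this share was fixed in advance and decides nothing, here and for the controls below. Between 24 h and 4 h controls the real split called 0 and all 10 splits gave as many; the highest other called 10437 and another 9002, which points to a structure of the samples.

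Probe sets with several symbols or none listed, used in no comparison, were tested in the same way, 6056 in all. Calls numbered 3 in A549, 11 in 16HBE14o-, 21 in CCL-153, 9 in CCL-151 at 4 h, 9 for epithelial against fibroblast lines and 12 for the mean of 4 lines.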

How the results depend on the processing

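The fits without CCL-151 controls a and c, after subtraction of other lines, of genes within 1 log2 between day 2 lines and of the 24 h arrays alone were chosen after seeing the data; the others were fixed before. Over all alternatives, list results kept their direction and side of the threshold in 3031 cases, passed it newly in 98, no longer passed in 314, moved in 172 and reversed in 53; for named genes these numbers were 2637, 90, 191, 56 and 17. Where no cause is given, the cause was not tested.

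Quantile normalization over all arrays called 17 genes in CCL-151 at 4 h and 2098 between its controls. Within days it called 71 genes in A549 and 127 in the 4-line mean. Testing fewer genes, above the 75th percentile, called 2764 between controls. Arrays of the same day alone gave 1 gene (HMOX1) for the 24 h against 4 h effect, 214 in A549, 722 in 16HBE14o- and 625 in CCL-153; arrays of the same line alone gave 1, 213, 770 and 848. Both leave arrays out of the estimate of spread.

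Array weights called 344 genes in A549, 564 in 16HBE14o-, 1474 in CCL-153, 4643 in CCL-151 at 4 h, 7057 at 24 h, 7190 between controls, 2715 for the 24 h against 4 h effect, 3120 for epithelial against fibroblast lines, 1977 in the 4-line mean, 4117 in the F-test and 14361 over pairs of lines; the weights did not settle, and the cause was not tested.

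A replicate block called 9 genes in A549, 136 in 16HBE14o-, 80 and 4 lists for epithelial against fibroblast lines, 39 in the 4-line mean, 135 in the F-test and 389 over pairs. The letters did not pair the arrays: deviations of same-letter arrays correlated at 0.0900 in CCL-153 and from -0.821 to 0.630 in CCL-151, across genes, which are not independent replicates.

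Without controls a and c, calls numbered 200 in A549, 671 in 16HBE14o-, 519 in CCL-153, 22 in CCL-151 at 4 h, 425 for epithelial against fibroblast lines, 732 in the 4-line mean, 769 in the F-test and 2008 over pairs, with 8 lists in CCL-151 at 4 h and 4 for the 24 h against 4 h effect. Controls a and c enter the comparisons within each day 2 line only through the shared estimate of spread, so the higher counts there came from that estimate. Lists called with or without controls a and c that reversed direction in the camera test follow, with their medians. For CCL-151 at 4 h these were actin -0.031, matrix -0.031, cell cycle -0.11, p53 targets -0.31, cholesterol synthesis -0.026, interferon 0.036, adhesion -0.038, ribosome -0.028, epithelial markers 0.30, basal and squamous markers 0.28, alveolar and club markers 0.41. For CCL-151 control time these were YAP and TAZ targets -0.16, actin -0.12, oxidative stress -0.15, heat shock -0.0033, p53 targets -0.10, epithelial markers 0.19, basal and squamous markers 0.22, alveolar and club markers 0.35. For 24 h against 4 h effect these were actin 0.067, oxidative stress 0.22, endoplasmic reticulum chaperones 0.073, cell cycle 0.16, interferon -0.12, adhesion 0.044, ribosome 0.028, epithelial markers -0.42, alveolar and club markers -0.61. For epithelial against fibroblast these were ribosome 0.13. For 4-line mean these were p53 targets -0.091, epithelial markers 0.14.

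After subtraction of other lines, calls numbered 28 in A549 (24 among the 34), 13 in CCL-151 at 4 h (10 among the 10), 87 in the 4-line mean (84 higher and 3 lower), 11 in 16HBE14o-, 15 in CCL-153, 0 for epithelial against fibroblast lines by limma (348 under an unadjusted p of 0.05; 15 lists, none of which passed with an estimated correlation, smallest adjusted p = 0.0506), 3 in the F-test and 4 over pairs. Named genes reversed there, their predicted signal having been removed. For A549 these were CFTR 0.52, IL1A 0.52, MACC1 0.24. For 16HBE14o- these were COL12A1 0.27, EDIL3 0.69, HGD -0.13, LOX 0.29, LRRC17 0.55, PCDH18 0.36, PLA2G4A -0.19, PTGS2 -0.086. For CCL-153 these were ANXA13 0.36, FGB 0.60, FGL1 0.65, HGD 0.36. For epithelial against fibroblast these were FGB -0.24, HGD -0.12. Lists called before or after it that reversed direction in the camera test also follow, with their medians. A median can differ in sign from that direction, as for the epithelial markers in CCL-153, which camera placed lower. For A549 these were epithelial markers 0.087. For 16HBE14o- these were actin 0.22, matrix 0.20, proteolysis 0.40, adhesion 0.16, ribosome -0.013, epithelial markers 0.18, endothelial markers -0.013, smooth muscle markers 8.87e-05. For CCL-153 these were oxidative stress 0.030, interferon -0.23, epithelial markers 0.031. For epithelial against fibroblast these were oxidative stress -0.15, matrix 0.0028, proteolysis 0.11, interferon 0.11, epithelial markers 0.22, basal and squamous markers 0.46, endothelial markers 0.13. For 4-line mean these were matrix 0.066.

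Among genes within 1 log2 between day 2 lines, which are fewer, calls numbered 14 in A549, 3 in 16HBE14o- (MT1M, MT1P3 and MT1X), 7 in CCL-153, 5 in CCL-151 at 4 h (BAK1, DNAJB1, MT1M, MT1X and SLC30A1), 26 in the 4-line mean, 1 over pairs (RAB33A), and by limma 0 for epithelial against fibroblast lines (178 under an unadjusted p of 0.05) and 0 in the F-test (122). The 24 h arrays alone called 1 gene (CEMIP).

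With an estimated correlation, lists called numbered 8 in A549, 5 in 16HBE14o-, 5 in CCL-153, 0 in CCL-151 at 4 h, 1 at 24 h, 0 between controls, 0 for the 24 h against 4 h effect, 1 for epithelial against fibroblast lines and 7 in the 4-line mean. By fry they numbered 7, 6, 5, 9, 0, 6, 2, 1 and 11 in that order, against 18, 14, 12, 17, 8, 13, 17, 7 and 19 at the preset correlation.

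Leaving out 1 of a comparison's own arrays at a time gave 11 to 16 genes in A549, 137 to 206 in 16HBE14o-, 59 to 102 in CCL-153, 4 to 10370 in CCL-151 at 4 h, 0 to 0 at 24 h, 0 to 11121 between controls, 0 to 7046 for the 24 h against 4 h effect, 92 to 5019 for epithelial against fibroblast lines, 45 to 3334 in the 4-line mean, 131 to 8806 in the F-test and 430 to 26112 over pairs. Each highest value from 5019 up, and the 3334, came without CCL-151 4 h control b. Lists called ranged from 5 to 11 for CCL-151 at 24 h, with 5 without 24 h control b. Arrays of other groups, which share the estimate of spread, were not left out in turn. The matrix list of the 4-line mean reversed from -0.052 to 0.036 without A549 stretched array B1 and to 0.017 without 16HBE14o- control C2.

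Without a filter, effects of A549 and CCL-153 correlated at 0.223. Over genes called in either line, correlations were -0.294 (A549 and 16HBE14o-), 0.437 (A549 and CCL-151 at 4 h), 0.545 (A549 and CCL-151 at 24 h), -0.291 (16HBE14o- and CCL-153), -0.0892 and 0.0617 (16HBE14o- and CCL-151 at 4 h and 24 h) and 0.504 and 0.420 (CCL-153 and CCL-151 at 4 h and 24 h).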

Other observations

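The tests in this part were all chosen after the results were seen. Some called rises on day 2 lay at least 1 log2 above every control array of that day, a level that RNA of an unstretched day 2 line would not reach. They numbered 2 in A549 (MT1F and MT1X), 12 in 16HBE14o- and 8 in CCL-153. Those in 16HBE14o- were 10 metallothionein genes or pseudogenes, ANKRD1 and SLC30A1, and those in CCL-153 included HSPA6 and MIR221.

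The stretched CCL-153 arrays differed in HSPA6, at 7.49 on B5 and 11.57 on C3.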
